A study of Homo sapiens with 6 samples.

How the data were processed

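The series profiled binding of the transcription factor p53 by chromatin immunoprecipitation and sequencing (ChIP-seq) in MCF-7, an established human breast carcinoma cell line. Per the labels, cells were given neocarzinostatin (NCS), a drug that cuts DNA and causes double-strand breaks, at 400 ng/mL for 3 h, or fresh medium for 3 h. Each condition has 2 biological replicates. The labels also list 2 samples of input DNA (sonicated chromatin without immunoprecipitation), which have no peak list of their own and enter only as the control of each peak call.

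Each of the 4 deposited lists was made by the authors with MACS2 2.1.1.20160309, per the file headers, from 1 ChIP library against 1 input library. Replicates were not pooled. Both lists of replicate 1 were called against one input library and both lists of replicate 2 against another, per the file headers. The headers give a q-value cutoff of 0.05, no fragment model, extension of every tag to 200 bp, at most 1 tag per position, and scaling of the larger library to the smaller. Bowtie2 2.2.5, bedtools and the genome build hg19 are named in the submitters' processing notes, without their settings. The step that produced the mapped reads before peak calling is otherwise not given in the sources used here.

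For each peak the deposited lists give start, end and summit in hg19 coordinates counted from 1. The deposited pileup is a coverage signal, the number of extended ChIP tags over the summit, in the ChIP library's own tags, because the input was the larger library in every call, per the file headers. The deposited fold enrichment is a ratio, the pileup + 1 over the background + 1, where the background is the largest of the genome-wide and local input levels. The deposited −log10 p-value comes from a Poisson test of the pileup against that background, and the deposited −log10 q-value is its adjusted form within a list. These values belong to the peak. Folds and −log10 values were used to describe, rank or filter peaks within a list, and folds of different lists are printed side by side as descriptions without a test. As alternatives, 1 −log10 p cutoff was applied to all lists, and folds took the place of pileups at sites called in all 4 lists.

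Depth was similar between conditions. The NCS-treated libraries held 27252306 and 28937182 tags after duplicate removal, and the untreated libraries held 27444544 and 30206665. The inputs held 31491052 tags for replicate 1 and 39146401 for replicate 2. Because at most 1 tag per position and strand was kept and tags were extended to 200 bp, a pileup cannot exceed 400.

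The background behind each fold was recovered from the deposited pileup and fold, and is given as a multiple of the list's genome-wide background. Peaks of different lists were called shared when they overlapped by at least 1 bp. Peaks of all 4 lists that overlapped, directly or through another peak, were merged into a site. Shares carry Wilson 95% intervals, which cover counting error only, since peaks of a library are not replicates. Chance overlap was taken from 100 random placements of the other list's peaks on the same chromosomes. Chromosome lengths of hg19 were not used here, so the span from the first to the last peak of all lists on each of 23 chromosomes (1 to 22 and X) stood in for the length, both for placements and for the expected peaks per chromosome. Peak counts were compared by an exact permutation test. Ranks within a list were compared by a permutation test with 100000 resamples, two-sided, and peaks per chromosome by a chi-square statistic with 10000 multinomial draws. Benjamini-Hochberg adjustment was applied over the lists of each test. The labels call the replicates biological and do not say what a shared replicate number means.

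At sites called in all 4 lists, the pileup was expressed per 1000000 tags of the library after duplicate removal. Treated and untreated counts summed over replicates were compared by an exact binomial test, two-sided, with adjustment over the sites and exact 95% intervals. This test covers counting error only, and it was chosen after the data were examined.

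The text names sites by a rule set before the data were examined, apart from those it marks as named after their values were seen. It takes the 20 sites in both NCS-treated lists with the highest mean percentile of fold enrichment, the 10 highest sites in both untreated lists, and up to 5 sites in both untreated lists and neither treated list. A rule for genes was dropped: the gene table at hand is on GRCh38.p14 and the lists are on hg19, so no peak was assigned to a gene and sites are named by coordinates. For the same reason the planned tests of p53 response elements, of position relative to genes and of fixed gene lists were not run.

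Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9. The procedures were tested on simulated lists. With 500 and 1500 overlaps planted among 2123 simulated treated peaks, 502 and 1501 were found. With a shift of 0.5 SD planted in a list of 2133 peaks, the rank test passed in 20 of 20 runs, and with none planted in 2 of 20. With the density of chromosome 17 doubled, the chromosome test passed in 20 of 20 runs for a list of 2133 peaks and in 3 of 20 runs for a list of 107. Alternatives were stricter cutoffs, other overlap rules, other ranking values, leaving out each library, and comparison within replicate numbers.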

Results

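Binding of p53, a transcription factor that accumulates after DNA damage, was mapped by ChIP-seq in MCF-7 breast carcinoma cells with and without DNA double-strand breaks. The design asked how p53 occupancy differs between cells given neocarzinostatin (NCS, 400 ng/mL for 3 h) and untreated cells. Each condition had 2 biological replicates with 1 deposited peak list each. After duplicate removal the treated libraries held 27252306 and 28937182 tags and the untreated libraries 27444544 and 30206665. All positions are on hg19, and every fold enrichment given for a peak is the authors' own value.

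NCS-treated cells had many more p53 peaks than untreated cells. The treated lists held 2133 peaks in replicate 1 and 2375 in replicate 2, a mean of 2254 ± 171 (SD, n = 2). The untreated lists held 107 and 73 peaks, a mean of 90 ± 24.0 (SD, n = 2). The ratio of the means was 25.04, and within replicate numbers, where both lists were called against the same input, the ratios were 19.9 and 32.5. The difference far exceeded the spread between replicates. An exact permutation test of 2 libraries against 2, two-sided, gave p = 0.333, the smallest value this design allows. Called peaks were also wider in treated cells, with median lengths of 313 and 315 bp against 250 and 251 bp. The treated lists reached down to −log10 p values of 5.62 and 4.77, and the untreated lists to 7.32 and 6.55. Whether this looser cutoff accounts for the wider peaks was not tested.

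**Figure D1:**
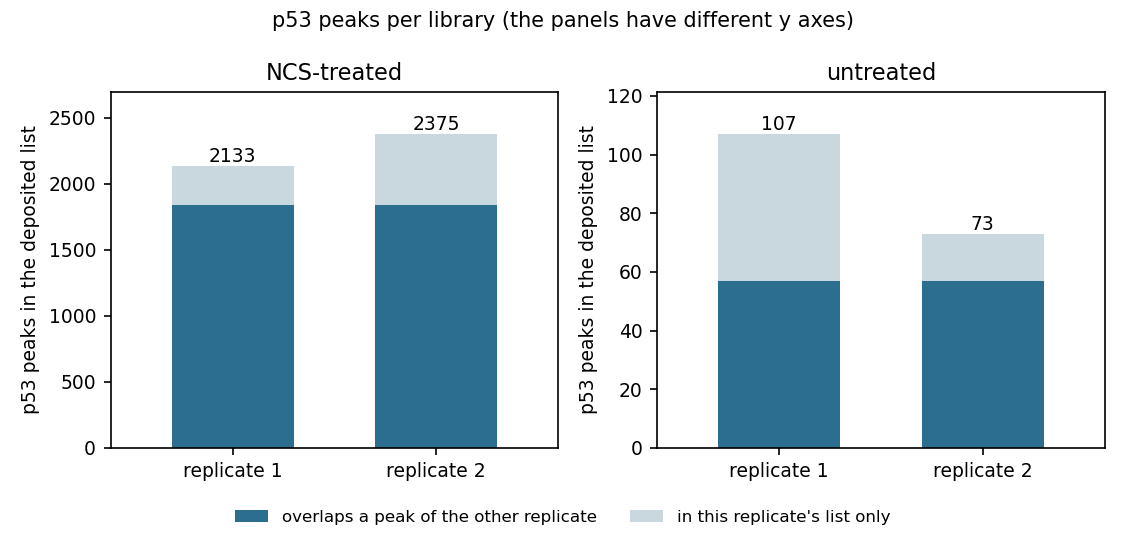
Number of p53 peaks per deposited list (y axis, which differs between the panels) for NCS-treated (left) and untreated (right) libraries, with the part that overlaps a peak of the other replicate in dark blue. The treated lists hold 2133 and 2375 peaks and the untreated lists 107 and 73.

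The treated replicates shared most of their sites. Of the replicate 1 peaks, 1835 of 2133 (86.0%, Wilson 95% interval 84.5 to 87.4) overlapped a replicate 2 peak, and 1838 of 2375 replicate 2 peaks (77.4%, 75.7 to 79.0) overlapped a replicate 1 peak. Random placement gave at most 0.283% and 0.212%. The summits of the 1838 overlapping pairs lay a median of 17 bp apart. Stronger peaks were shared more often. In the top decile of fold enrichment, 100% of the peaks of either list were found in the other. In the lowest decile the share was 65.7% (59.1 to 71.8) for replicate 1 and 44.7% (38.5 to 51.1) for replicate 2, and the lowest share in replicate 1 was 62.8% (56.0 to 69.1), in the decile above it. The untreated lists had 57 peaks in common, which was 53.3% (43.9 to 62.4) of replicate 1 and 78.1% (67.3 to 86.0) of replicate 2.

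**Figure D2:**
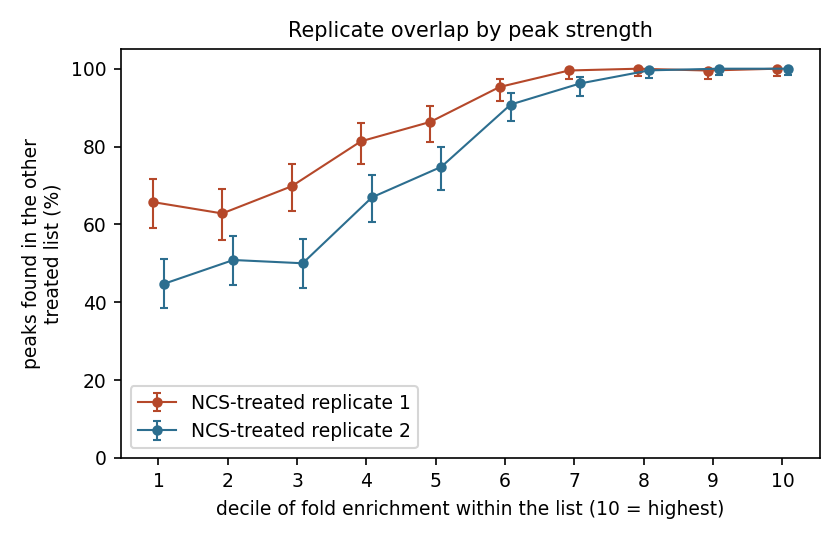
Share of peaks in each NCS-treated list that overlap a peak of the other NCS-treated list (y axis, percent) by decile of fold enrichment within the list (x axis), with Wilson 95% intervals as bars. The share is 65.7% and 44.7% in the lowest decile and 100% in the highest.

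The 4 lists merged into 2676 sites, and the sites found in both treated libraries were mostly absent from the untreated lists. Of 1835 sites in both treated lists, 1735 (94.6%, Wilson 95% interval 93.4 to 95.5) had no peak in either untreated list. A further 48 had a peak in 1 untreated list and 52 had a peak in both. Absence from a list means only that the site did not pass the cutoff there. The smallest pileup called in an untreated list was 17 tags in replicate 1 and 21 in replicate 2, and among peaks at the genome-wide background it was 17 and 24. Of the 1735 treated-only sites, 1221 had pileups above 24 in both treated libraries, and 773 had pileups above 36, the larger of the 2 untreated median pileups. Both counts disregard local background, and a site with a higher background needs more tags to be called. With peaks of a −log10 p of at least 20 only, the count of treated-only sites was 1006.

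The 20 strongest sites in both treated lists lay on 15 chromosomes, with the authors' fold enrichments between 35.6 and 64.9. The strongest lay on chromosome 1 from 72466334 to 72467000, with folds of 64.9 and 64.3 in treated replicates 1 and 2. It also had a peak in untreated replicate 1, with a fold of 9.56. A site on chromosome 9 from 124084564 to 124085232 had treated folds of 46.8 and 53.6. On chromosome 3, the site from 83983400 to 83984284 had treated folds of 51.02 and 49.9. The site on chromosome 12 from 69202488 to 69203038 had treated folds of 41.7 and 55.8 and a fold of 5.97 in untreated replicate 1. On chromosome 6, the site from 36643799 to 36644650 had treated folds of 54.0 and 43.6 and untreated folds of 5.81 and 7.11. Among the 20, 7 had no untreated peak, led by a site on chromosome 7 from 40756896 to 40757361 with folds of 49.0 and 49.3, and followed by one on chromosome 9 from 136746038 to 136746827 with folds of 48.9 and 47.3. On chromosome 16, the site from 4190446 to 4191438 also lacked an untreated peak and had treated folds of 41.9 and 50.9. The other 13 had a peak in at least 1 untreated list, where their folds ranged from 5.23 to 10.6.

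Nearly every peak of the untreated cells was also a peak of the treated cells. Of the untreated replicate 1 peaks, 102 of 107 (95.3%, Wilson 95% interval 89.5 to 98.0) overlapped a peak of either treated list, and of the replicate 2 peaks 71 of 73 (97.3%, 90.5 to 99.2) did. Random placement gave at most 1.90% and 2.78%. Against the treated list called with the other input, the shares were 89.7% for untreated replicate 1 and 86.3% for untreated replicate 2. Only 6 sites had an untreated and no treated peak. One of them was in both untreated lists, on chromosome 19 from 18557866 to 18558091, with folds of 6.59 and 6.35. The others, named after their values were seen, lay on chromosome 10 from 127313444 to 127313646, chromosome 11 from 647770 to 648040, chromosome 14 from 104159870 to 104160085, chromosome 20 from 35215762 to 35215977 and chromosome 20 from 24630632 to 24630861, with folds between 5.37 and 7.44.

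All of the 10 strongest sites in both untreated lists were also called in both treated lists. The strongest lay on chromosome 17 from 38604926 to 38605275, with the authors' folds of 24.8 and 29.1 in untreated and 23.1 and 32.7 in treated replicates 1 and 2. On chromosome 11, the site from 1817617 to 1818168 had folds of 34.9 and 28.98 in untreated and 24.7 and 36.8 in treated cells. The site on chromosome 21 from 43796419 to 43796762 had folds of 17.2 and 16.3 in untreated and 14.8 and 16.7 in treated cells. On chromosome 12, the site from 2905084 to 2905392 had untreated folds of 21.8 and 13.7 and treated folds of 11.6 and 10.4. The site on chromosome 1 from 181103729 to 181104694 had untreated folds of 15.6 and 15.6 and treated folds of 34.9 and 55.4.

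The 52 sites called in all 4 lists fell into separate sets by summit pileup per 1000000 tags. At 11 sites the mean treated pileup was at least 2 times the mean untreated pileup, with ratios from 2.58 to 7.75 and a median of 5.82. At all 11 both treated values lay above both untreated values. The median of the 11 was 7.97 in treated and 1.27 in untreated cells. At 38 sites the means lay within 1.5-fold of each other, with ratios from 0.733 to 1.34, and their median was 1.63 in treated and 1.68 in untreated cells. The remaining 3 sites had lower treated pileups, with ratios down to 0.617, and no site had a ratio between 1.34 and 2.58. These limits of 2 and 1.5 were set after the values were seen.

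**Figure D3:**
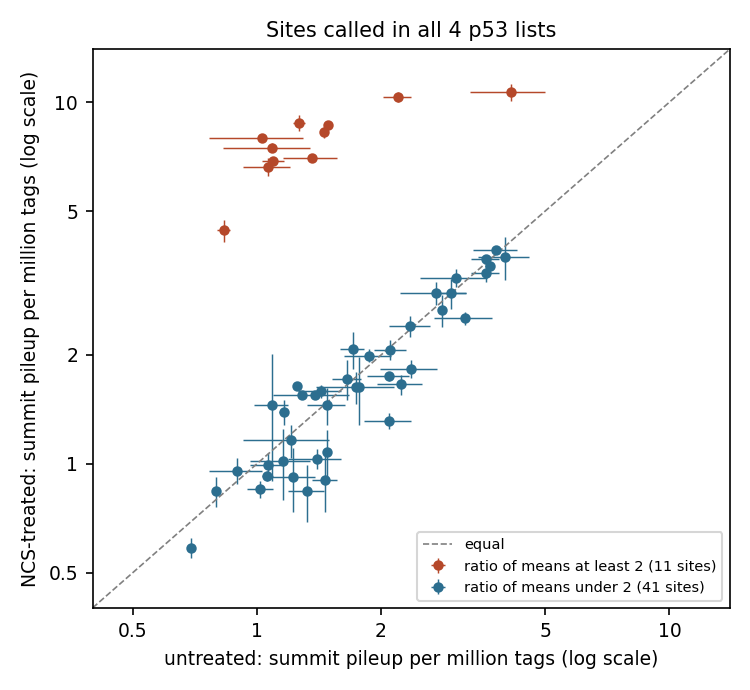
Summit pileup per 1000000 tags at the 52 sites called in all 4 lists, untreated (x axis, log scale) against NCS-treated (y axis, log scale), with points at the mean of 2 replicates, bars from the lower to the higher replicate and a dashed line where both are equal. The 11 red sites have treated means at least 2 times the untreated means, and the 41 blue sites lie nearer the line.

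The largest ratio among the 52 was at the site on chromosome 6 from 36643799 to 36644650. Its pileup per 1000000 tags was 7.78 and 8.16 in treated and 0.765 and 1.29 in untreated cells, a ratio of 7.75 (exact binomial 95% interval 5.84 to 10.2). The site on chromosome 14 from 67398985 to 67400020 had a ratio of 6.92 (5.42 to 9.00), and the site on chromosome 12 from 125422999 to 125424031 had a ratio of 6.88 (5.33 to 9.25). The lowest ratio of the 11, 2.58 (2.23 to 3.04), was at the site on chromosome 1 from 181103729 to 181104694. The strongest untreated site, on chromosome 17 from 38604926 to 38605275, had a ratio of 1.03 (0.846 to 1.26). On chromosome 12, the site from 2905084 to 2905392 had a ratio of 0.628 (0.467 to 0.852). By the exact binomial test, which covers counting error only, 11 of 52 sites were higher in treated cells, with adjusted p of at most 1.47e-34. It placed 2 sites lower, the site on chromosome 12 starting at 2905084 with an adjusted p of 0.00846 and a site on chromosome 1 starting at 112056086, named after its values were seen, with an adjusted p of 0.03. Both treated values lay above both untreated values at 15 sites and below both at 12. Chance gives 16.7% of the 52, or 8.67 sites, in each direction if the 4 libraries are exchangeable at every site, whatever their replicate number. The 15 include all 11 sites with a ratio of at least 2, and the 12 all lay among the other 41. Among those 41, both untreated values were therefore the higher ones at more sites than both treated values were. All 52 sites had to pass the cutoff in untreated cells to be included.

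Peaks that treated and untreated cells had in common ranked higher within the treated lists than the other peaks did. In treated replicate 1, the 106 peaks that overlapped an untreated peak had a mean fold percentile of 62.2 ± 33.4 (SD over peaks), and the other 2027 had 49.4 ± 28.5. In treated replicate 2 the means were 62.8 ± 33.2 for 111 peaks and 49.4 ± 28.5 for the other 2264. The permutation test, two-sided, gave an adjusted p of 1e-05 in each list, the smallest that 100000 resamples give. It describes each list and has no sample replicates. A shared peak also had to pass the cutoff in untreated cells. The smallest pileup called there was 17 and 21 tags, against 12 and 11 in the treated lists. A higher mean rank of shared peaks may follow from this cutoff alone, which was not tested. The shared peaks were not confined to the top of either list, though fewer than 50% of them were in the lower 50%. In treated replicate 1, 35 of the 106 were in the top decile and 39 were in the lower 50%, and in replicate 2 the counts were 35 and 37 of 111.

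Peaks were unevenly spread over the chromosomes in all 4 lists. Chromosome 17 held 4.71% (Wilson 95% interval 3.89 to 5.70) and 4.72% (3.93 to 5.65) of the treated peaks and 9.52% (5.26 to 16.6) and 13.9% (7.72 to 23.7) of the untreated peaks, where its span predicts 2.73%. Chromosome 19 held 7.62% and 8.33% of the untreated peaks and 2.64% and 2.97% of the treated peaks, with 1.99% predicted. Chromosome 20 held 3.30% and 3.10% of the treated peaks, with 2.12% predicted. Fewer treated peaks than predicted lay on chromosome X (2.97% and 3.02%, with 5.20% predicted), chromosome 13 (1.70% and 1.95%, with 3.29% predicted) and chromosome 18 (1.41% and 1.32%, with 2.44% predicted). The chi-square test with multinomial draws gave an adjusted p of 0.0001 in each list, the smallest that 10000 draws give. Treated and untreated shares were not tested against each other.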

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

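Of 127 recomputed values, 119 stayed on the same side of their test's threshold or within the spread, interval or 1.5-fold range of the main value, and 8 moved. The alternatives with a −log10 p of at least 20 and with 1 p-value cutoff for all lists were chosen after the data were examined. So were those without peaks in high local background. The same holds for all alternatives for the pileup at sites in all 4 lists and for the 20 named treated sites. With a −log10 p of at least 20, the overlap of treated replicate 1 was 90.2% and of treated replicate 2 81.1%, that of untreated replicate 2 was 88.4%, the share of untreated replicate 1 found in treated cells was 82.5%, and treated-only sites numbered 1006 in place of 1735. The overlap of treated replicate 1 was 83.9% with a fold of at least 5 and 84.4% with summits within 100 bp. The cause was not tested for any of these shares, and the lower count follows from the fewer peaks. Leaving out 1 treated library gave 86.3% to 94.5% for the untreated replicate 2 peaks found in treated cells, where fewer lists leave fewer peaks to overlap. Leaving out each of the 4 libraries gave ratios of peak counts from 21.1 to 30.9. Treated-only sites numbered 1774 and 1744 without untreated replicate 1 or 2. Without treated replicate 1 or 2 the counts were 2264 and 2027. These count sites in the 1 treated list left, where the main count asks for both, so they are not directly comparable. With a replicate block, values within replicate numbers gave a ratio of peak counts of 25.5, shares of untreated peaks found in treated cells of 91.6% and 94.5%, and rank differences of 12.9 and 14.1 percentile points with permutation adjusted p of 6e-05 and 0.00012. The block changed no call. The number of sites in all 4 lists with a treated value at least 2 times the untreated one was 11 with the authors' folds in place of pileups. All 20 named treated sites were in both treated lists under the 8 filters and overlap rules run. They were picked as the strongest sites in both lists, so this outcome was largely fixed in advance and shows no stability. These 8 values are counted among the 119. Not run, for want of hg19 sequence or annotation, were all alternatives for p53 response elements, position relative to genes and gene lists, and the expectation of peaks per chromosome from gene number. The smallest pileup called was 17 tags in untreated replicate 1 and 21 in untreated replicate 2, so these lists do not show whether sites with fewer tags were occupied in untreated cells.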

Other observations

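The tests of sequencing depth, input library, high local background and copy number, and the pileup comparison itself, were chosen only after the results were seen, and signal that does not depend on p53 was raised then and not tested. The sites called in both treated lists and in neither untreated list lay close together more often than random placement gives. Of 1729 such sites on chromosomes 1 to 22 and X, 239 (13.8%) lay within 50 kb of another, and 100 random placements gave a mean of 6.12% and at most 7.69%. Some neighbouring sites lay so close together that a single bound region called as separate peaks may add to this share. Such splitting was not tested. The densest megabase, named after its values were seen, held 14 sites, on chromosome 8 from 86560364 to 86833620, where the placements gave at most 7 in any megabase. From 80 to 90 Mb on chromosome 8 the treated lists held 20 and 21 peaks in replicates 1 and 2. The median implied input background of these peaks was 9.20 and 9.01 times the genome-wide level.

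At the 48 sites in both treated lists and 1 untreated list, 23 had a treated pileup at least 2 times the untreated one and 23 had values within 1.5-fold, with ratios from 0.772 to 7.42. The remaining 2 had ratios between 1.5 and 2, and the median of the 48 was 1.71. The gap in ratios seen at the sites called in all lists was therefore not empty at these sites. These sites had 1 untreated value each, from the library in which the site was called, so the ratios have no untreated spread. The other untreated library, where the site did not pass the cutoff, was left out. The untreated values may therefore be too high and the ratios too low.

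Treated lists held more peaks than untreated lists. The tables argue against sequencing depth as the cause, since the treated libraries had 0.975 times the mean tags of the untreated ones. With 1 p-value cutoff for all lists, the ratio of mean peak counts was 24.9, and within replicate numbers, where the input is the same, the lower ratio was 19.9. The NCS treatment, which the design names, and a difference in immunoprecipitation efficiency between conditions both stay open, and neither was tested apart from the other.

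At 38 sites called in all 4 lists, treated and untreated pileups were alike. High local input background may raise both. The median implied background, averaged over the 4 lists, was 1.61 times the genome-wide level at these sites. That was 0.825 times the median of 1.95 at the 11 sites with higher treated pileup. Peaks of all 4 lists with a fold of at least 3 had a median of 1.29 times. As the 11 sites were themselves above that level, the comparison with them cannot exclude a part for local background. Signal that does not depend on p53, such as open chromatin caught in any pulldown, stays open for the 38 sites, because no list from cells without p53 or from a control antibody was analysed here. Occupancy by p53 that NCS does not change is the other open explanation, and these lists cannot separate the pair.

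Treated sites were unevenly placed along the genome. Sequence at more than 2 times the genome-wide background did not account for all of the close spacing. Without such sites, 10.7% of 1406 still lay within 50 kb of another, and placements gave at most 7.89%. This cannot exclude sequence in many copies for the sites removed, or smaller gains for those kept. The only megabase with more sites than any placement gave held 14 sites and lay on chromosome 8 between 80 and 90 Mb. The 20 and 21 treated peaks in those 10 Mb had median backgrounds of 9.20 and 9.01 times the genome-wide level. As the background was read at peaks, these medians may describe the dense megabase more than the whole 10 Mb. Density that varies over megabases was tested by moving each site at random within 1 Mb, and 0 of 100 such placements reached the observed share. As whole sites were placed each time, the placements cannot separate close binding sites from a single region called as separate peaks. That explanation stays open. Copy number gains may contribute to the differences between chromosomes: over 23 chromosomes, peak density and median implied background had a Spearman rho of 0.603 (permutation adjusted p 0.00556) and 0.501 (0.0158) in the 2 treated lists, and a Pearson r of 0.634 (adjusted p 0.00204) and 0.559 (0.00544). Without chromosomes 14 and 20, rho was 0.490 and 0.437 and r was 0.562 and 0.511, and no p was computed for these. Chromosomes are not independent replicates, the background was read at peaks only, and gene density stays open as an untested explanation.

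Some peaks had low fold or the highest possible pileup. Over the 4 lists, 59 peaks had a fold under 3, of which 44 were in treated replicate 2. Of the 59, 58 had an implied background of more than 5 times the genome-wide level, with a median of 106.9 times against 1.29 times for the other peaks, and 19 overlapped a peak of the other replicate. As the fold divides by this background, a low fold and a high background go together by construction. In all, 4 peaks had a pileup of 400, of which 2 were in treated replicate 2 and 2 in untreated replicate 2.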
